A study of Mus musculus with 36 samples.

How the data were processed

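Poly(A) RNA-seq libraries were analysed, 16 from mouse embryonic stem cells (mESCs) and 20 from mouse tissue samples. The mESCs carried an empty vector (EV) or a rat L2HGDH cDNA and were labelled untreated, for which the protocol names a vehicle, or were given 500 nM myxothiazol, an inhibitor of respiratory complex III, for 16 hours. This gave 4 groups of 4 libraries. Kidney and liver came from the same 10 animals, 5 homozygous for L2HGDH overexpression and 5 wild-type. The labels do not give the age of the animals, so it is not known whether the genotypes were matched for age. The labels do not say whether the 4 mESC libraries of a group are separate cultures, so their p-values measure the spread between these libraries, which may be technical.

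The deposited values are whole-number counts per gene, not normalized by the authors. The submitters' processing notes name STAR and Salmon, without versions, and the mouse build GRCm38 (mm10); how strand and reads shared by near-identical genes were handled is not given in the sources used here. Zscan4, Usp17l and hemoglobin genes are paralogs that can share reads, and their single values are uncertain. Each table holds 45706 genes, and 45143 of their identifiers (98.8%) are in GENCODE release M21 for GRCm38, from which chromosomes and positions were taken. Library totals were 15771907 to 18472293 counts in mESCs, 30282277 to 33829877 in kidney and 12513238 to 16267394 in liver. Deposited metadata tables that only repeat the labels were not used. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 6.21 to 280 over genes with at least 20 counts in the pair.

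Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, robust dispersion estimates and the quasi-likelihood F test, with only the libraries of the groups compared in each fit. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All adjusted p-values of genes come from this test unless another tool is named. Log2 fold changes are given with the standard error derived from the F statistic, and levels as CPM, counts scaled to the library total. The interaction in mESCs compared the cDNA effect with and without myxothiazol over 16 libraries, and the tissue interaction compared the genotype effect in kidney and liver over 20 libraries. Gene lists (17 for mESCs, 27 for kidney and 30 for liver), the tests and the rule for naming genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 3 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Lists with fewer than 3 measured members were left out, which left 26 lists for kidney; 19 lists were tested for the tissue interaction.

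L2hgdh and D2hgdh are always named. In each comparison up to 8 risen and up to 8 fallen genes are named. They have the largest fold changes among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, which chance gives for 2.86% of genes with 4 against 4 libraries and 0.79% with 5 against 5. Up to 2 called members of each list are added. Where fewer than 10 genes were called, up to 10 genes with the smallest unadjusted p and the same CPM minimum are named. The interactions leave out the condition on overlap. Predicted genes, RIKEN clones and pseudogenes are not named. A named gene or list member may be given in other comparisons of its system.

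Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, each library left out in turn, the replicate number or animal as a block, a fit over all libraries of the system, sex as a covariate in tissues, and for lists an estimated correlation and fry. The sex of each mouse was read from Xist and Ddx3y counts, which gave the same sex in kidney and liver of all 10 animals, with 3 males and 2 females overexpressing L2HGDH and 2 males and 3 females wild-type. Chosen after seeing the data were fits without chosen animals, list tests with sex as a covariate or without chosen animals, and fits and list tests without chromosomes 3, 6, 8 and Y. Kidney and liver of the same animal are paired: their deviations from the group means correlated between 0.02 and 0.29, and 8 of 10 kidneys correlated best with their own liver. The steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, all drawn from genes with a mean above 5 CPM. The fit recovered 96% and 97% of them for the cDNA in untreated mESCs (13997 genes) and 93% and 98% under myxothiazol (14091 genes). It recovered 93% and 98% for myxothiazol in EV cells (13917 genes) and 93% and 99% in L2HGDH cells (14217 genes). For the mESC interaction it recovered 78% and 98% (14793 genes), for kidney 74% and 99% (16306 genes), for liver 74% and 94% (12996 genes) and for the tissue interaction 46% and 91% (16483 genes). Unchanged genes made up 16 of 209 calls on the simulated counts for the cDNA in untreated mESCs, and 4 to 12 calls in each other comparison. Genes were simulated independently of each other, and the adjusted threshold depends on how many genes change. The shares recovered therefore do not give the power on the real tissue counts, where few genes were called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.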

Results

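RNA from 36 libraries was compared to ask how L2HGDH, the enzyme that oxidises L-2-hydroxyglutarate to 2-oxoglutarate, alters gene expression. Mouse embryonic stem cells, the pluripotent cells of the early embryo, carried an empty vector (EV) or a rat L2HGDH cDNA, with or without 500 nM myxothiazol for 16 hours (n = 4 libraries per group, 15771907 to 18472293 counts each). Kidneys (30282277 to 33829877 counts) and livers (12513238 to 16267394 counts) came from 5 homozygous L2HGDH-overexpressing and 5 wild-type mice.

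L2hgdh (ENSMUSG00000020988; chromosome 12, 69690433 to 69724873, GRCm38, GENCODE M21) was higher in every library that should carry extra L2HGDH than in every control of the same system. In untreated mESCs it measured 235 ± 8.14 CPM with the cDNA and 28.2 ± 2.11 CPM with EV (SD, n = 4 each), a log2 fold change of 3.06 ± 0.05 (SE, adjusted p = 2.8e-09). Under myxothiazol the levels were 183 ± 2.65 and 25 ± 0.812 CPM (SD, n = 4 each; log2 fold change 2.87, adjusted p = 9.65e-11). Kidney L2hgdh was 990 ± 161 CPM in overexpressing and 50.9 ± 16.2 CPM in wild-type mice (SD, n = 5 each; log2 fold change 4.15, adjusted p = 0.000296). Liver L2hgdh was 303 ± 84.1 against 20.7 ± 2.78 CPM (SD, n = 5 each; log2 fold change 3.86, adjusted p = 1.41e-05). Myxothiazol lowered L2hgdh in L2HGDH cells (log2 fold change -0.36, adjusted p = 2.18e-05). In EV cells it fell by 0.18 (adjusted p = 0.0458), a call lost when any of 7 of the 8 libraries was left out, all but untreated EV 2. The mESC cDNA is from rat, so counts of the mouse gene include its reads only as far as they matched the mouse sequence. D2hgdh, which encodes the enzyme for the D enantiomer, was not called in any comparison, and in untreated EV cells it varied widely (36.9 ± 30.1 CPM, SD, n = 4).

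**Figure D1:**
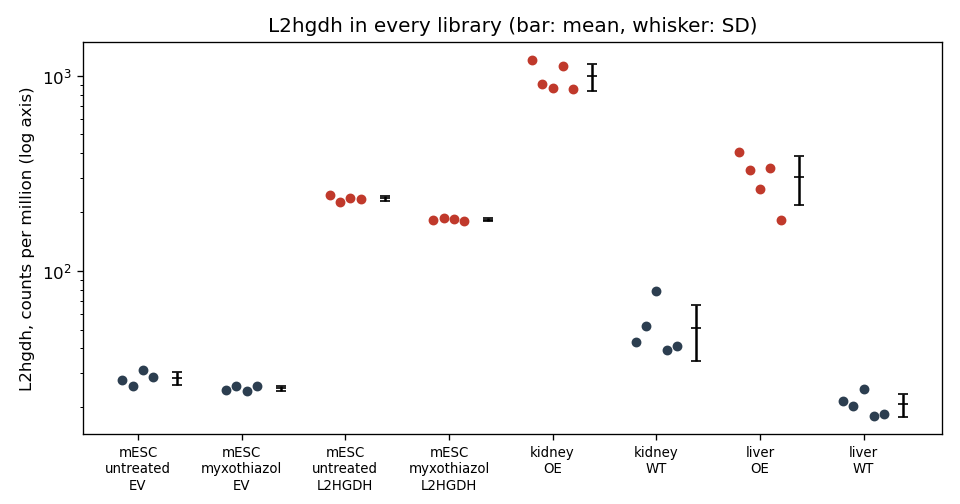
L2hgdh level in CPM (log axis) in each of 36 libraries, by group; points are libraries, with the mean and SD beside them (OE, overexpressing; WT, wild-type). Kidney means were 990 CPM in overexpressing and 50.9 CPM in wild-type mice.

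Under myxothiazol, in EV cells 2880 genes rose and 2725 fell, of 13917 tested, and in L2HGDH cells 2862 rose and 2704 fell, of 14217. Targets of ATF4, the transcription factor of the integrated stress response, rose throughout: 33 of 33 measured members in EV cells and 34 of 34 in L2HGDH cells (33 and 34 adjusted over the list alone), with medians of 0.99 and 1.02 on the log2 scale. Cebpb, a transcription factor gene, went from 5.65 ± 0.349 to 39.4 ± 4.59 CPM in EV cells (SD, n = 4 each; log2 fold change 2.79 ± 0.10 SE, adjusted p = 9.78e-08). Atf3 rose by 2.77 ± 0.17 in EV cells and Stc2, which encodes a secreted glycoprotein, by 2.65 ± 0.10 in L2HGDH cells. The camera test of this list gave adjusted p = 4.22e-25 in EV and 1.8e-23 in L2HGDH cells. With an estimated correlation the adjusted p was 0.056 and 0.15.

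Sterol synthesis genes also rose, 23 of 24 members in each cell population (23 and 23 adjusted over the list alone; medians 0.98 and 0.97). Pcsk9, which lowers LDL receptor levels, rose by 2.55 ± 0.09 and 2.61 ± 0.08, and Lss, encoding lanosterol synthase, by 1.53 ± 0.15 and 1.47 ± 0.07 (log2, SE). The list gave adjusted p = 9.27e-18 and 7.57e-17, and adjusted p = 0.056 and 0.11 with an estimated correlation.

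Respiratory chain and glycolysis genes moved both ways. Of 76 nuclear-encoded respiratory chain genes, 26 fell and 7 rose in EV cells, and 25 fell and 12 rose in L2HGDH cells. Uqcrh, a complex III subunit gene, fell by 0.60 ± 0.06 and 0.78 ± 0.05 on the log2 scale. This list passed camera in EV cells (adjusted p = 0.0126, and adjusted p = 0.57 with an estimated correlation) and not in L2HGDH cells (adjusted p = 0.0753). In the camera test of the interaction, which compares these responses, it did not pass (adjusted p = 0.319). Of 13 mitochondrially encoded mRNAs, 10 rose and 1 fell in EV cells, and 6 rose and 1 fell in L2HGDH cells (adjusted p = 0.00402 and 0.0389, and adjusted p = 0.53 and 0.61 with an estimated correlation). mt-Co1 rose by 0.55 ± 0.04 and 0.52 ± 0.04, while mt-Cytb fell by 0.20 and 0.29. In glycolysis 12 of 20 genes fell in each population, and 6 and 5 rose. Ldha, encoding a lactate dehydrogenase subunit, went from 490 ± 21.3 to 190 ± 9.82 CPM in EV cells (SD, n = 4 each; log2 fold change -1.37 ± 0.05 SE, adjusted p = 1.01e-07), and Aldoc rose by 1.00 ± 0.09. The glycolysis list did not pass (adjusted p = 0.114 and 0.0753).

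Among the strongest single changes, Trim66, a chromatin-associated TRIM family gene, rose from 0.781 ± 0.0813 to 14 ± 1.37 CPM in EV cells (SD, n = 4 each; log2 fold change 4.15 ± 0.14 SE) and by 3.42 ± 0.15 in L2HGDH cells. Eln, encoding elastin, rose by 4.72 ± 0.36 and 3.67 ± 0.21, and B4galnt2 by 2.86 ± 0.15 and 3.18 ± 0.13. In L2HGDH cells Prph, Acot2 and Ahnak2 rose by 2.79, 2.65 and 2.64. Genes that fell in both populations were Ano1 (-2.37 and -1.58), Steap3 (-1.64 and -1.57), Nlrc4 (-1.63 and -1.54), Myo1f (-1.60 and -1.58) and Cdx2, a trophoblast transcription factor gene (-1.72 and -2.08). Formative and primed pluripotency genes fell for 8 of 14 members in each population, among them Sox3 (-0.88 in EV cells) and Dnmt3a (-1.07 in L2HGDH cells), while Fst rose by 1.45 and 1.44. That list passed camera in L2HGDH cells (adjusted p = 0.0389, and adjusted p = 0.31 with an estimated correlation) but not in EV cells (adjusted p = 0.0625). Its medians were -0.36 and -0.29, and it did not pass camera in the interaction (adjusted p = 0.818). Of 2-cell-like genes, normally active at the time of zygotic genome activation, 11 of 16 fell in L2HGDH cells (adjusted p = 8.46e-05, and adjusted p = 0.34 with an estimated correlation). In EV cells, where fewer members passed the low-count filter, 2 of 10 fell (adjusted p = 0.0794). The medians were -0.89 in L2HGDH and -0.69 in EV cells. In the camera test of the interaction, which compares these responses, the 2-cell-like list did not pass (adjusted p = 0.0711). Among HIF targets 9 rose and 9 fell of 25 in EV cells, Vegfa rising by 1.77 ± 0.18, and 9 rose and 7 fell of 24 in L2HGDH cells, Ndrg1 rising by 2.08 ± 0.28.

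**Figure D2:**
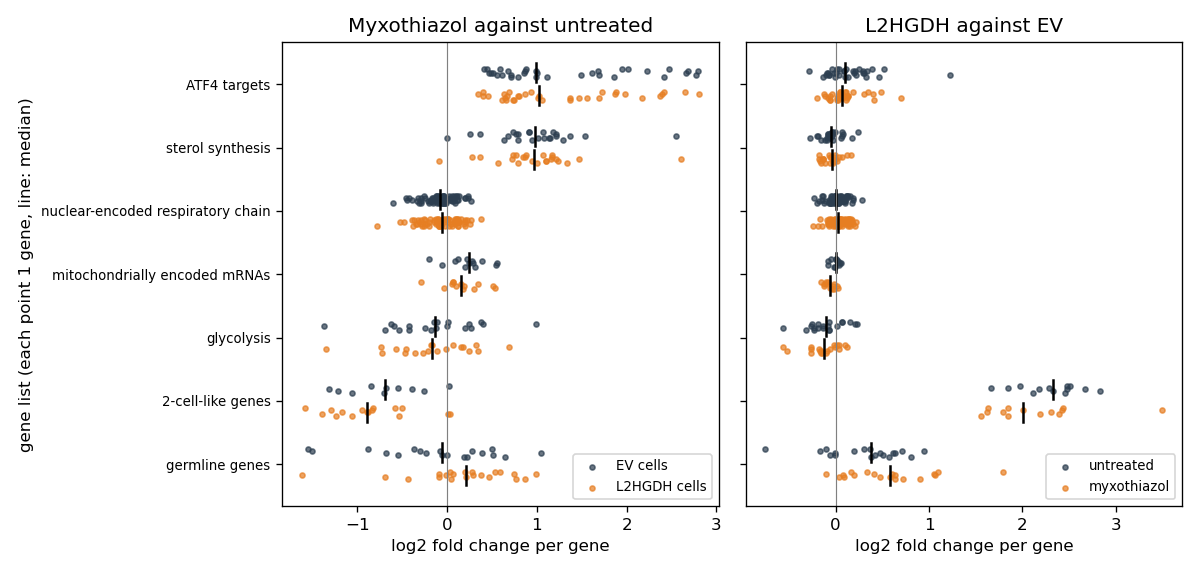
Log2 fold change of each gene (points) and median (line) for 7 gene lists in mESCs; left, myxothiazol against untreated in EV and L2HGDH cells, right, L2HGDH against EV without and with myxothiazol. ATF4 targets had medians of 0.99 and 1.02 on the left.

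The EV and L2HGDH responses share no library. Of 13737 genes tested in both, 2197 rose and 2080 fell in both, against 592 and 527 for independent lists, and 0 were called in opposite directions. The log2 fold changes correlated across genes with Pearson's r = 0.78 and Spearman's rho = 0.77; genes are not independent replicates.

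With the L2HGDH cDNA fewer genes were called in mESCs. Without myxothiazol 777 genes rose and 671 fell, of 13997, and with myxothiazol 741 rose and 651 fell, of 14091. 2-cell-like genes rose for 12 of 13 members without and 13 of 13 with myxothiazol (13 and 13 adjusted over the list alone; medians 2.33 and 2.00 on the log2 scale). Zscan4f was 36.3 ± 8.38 CPM with L2HGDH and 5.66 ± 0.908 CPM with EV in untreated cells (SD, n = 4 each; log2 fold change 2.67 ± 0.18 SE, adjusted p = 7.45e-05) and 12.2 ± 3.24 against 3.48 ± 1.48 CPM under myxothiazol. Zscan4b, Zscan4d, Usp17lc and Usp17le rose by 2.83, 2.51, 2.48 and 2.48 in untreated cells. These families can share reads, so single members are uncertain. The list gave adjusted p = 2.62e-15 and 1.24e-13, and adjusted p = 0.063 and 0.014 with an estimated correlation. Without chromosomes 3, 6, 8 and Y it passed in both treatments with an estimated correlation (adjusted p = 0.04 and 0.011).

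Germline genes rose for 3 and fell for 1 of 19 in untreated cells, and rose for 6 of 19 with myxothiazol (6 and 12 higher, and 1 and 1 lower, adjusted over the list alone; adjusted p = 0.0034 and 5.51e-07, and adjusted p = 0.16 and 0.047 with an estimated correlation). Dazl, an RNA-binding protein gene of germ cells, rose by 0.95 ± 0.07 in untreated cells, and Sycp1, on chromosome 3, and Mov10l1 rose by 1.06 ± 0.16 and 1.79 ± 0.37 under myxothiazol; the Mov10l1 call was lost without EV 2 or EV 3. Without chromosomes 3, 6, 8 and Y the germline list passed camera in both treatments (adjusted p = 0.00669 and 2.72e-06), but the adjusted p with an estimated correlation was 0.14 and 0.085. Glycolysis genes fell for 6 and 9 of 20 (10 and 10 lower, and 2 and 0 higher, adjusted over the list alone; adjusted p = 0.00888 and 0.00135, and adjusted p = 0.50 and 0.28 with an estimated correlation), Ldhb by 0.56 ± 0.06 and 0.52 ± 0.04. Of these, 5 and 5 lay on chromosomes 3 or 6, and without chromosomes 3, 6, 8 and Y the list did not pass (adjusted p = 0.468 and 0.0564). ATF4 targets rose for 7 of 33 and 9 of 34, with 1 fallen under myxothiazol (8 and 11 higher, and 0 and 1 lower, adjusted over the list alone; adjusted p = 0.00527 and 0.00562, and adjusted p = 0.50 and 0.48 with an estimated correlation), Aars, on chromosome 8, by 0.52 and 0.48; without those chromosomes the adjusted p was 0.0101 and 0.0112, and adjusted p = 0.56 and 0.48 with an estimated correlation. Hox genes passed camera (adjusted p = 0.00141 and 0.00489, and adjusted p = 0.063 and 0.075 with an estimated correlation) on 2 of 12 and 1 of 15 risen genes (3 and 3 adjusted over the list alone). Without those chromosomes the Hox list had adjusted p = 0.04 and 0.085 with an estimated correlation, so it passed in untreated cells. Under myxothiazol p53 targets (5 of 21 risen, adjusted p = 0.0292) and fibroblast markers (3 of 7 risen, adjusted p = 0.0361) passed too (5 and 4 higher, and 1 and 1 lower, adjusted over the list alone), with adjusted p = 0.24 and adjusted p = 0.20 with an estimated correlation.

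Fallen genes included Ylpm1 (chromosome 12; 303 ± 21.7 to 104 ± 7.42 CPM in untreated cells, SD, n = 4 each; log2 fold change -1.54 ± 0.06 SE, adjusted p = 3.04e-06), the Wnt effector gene Lef1 on chromosome 3 (-1.57 ± 0.19), the imprinted gene Mest on chromosome 6 (-0.89 ± 0.03), Sox21 (-1.22 ± 0.13), Hif3a (-1.75 ± 0.30) and Mobp (-2.48 ± 0.20). Under myxothiazol Ylpm1, Lef1, Mest and Sox21 fell by 1.80, 1.47, 0.90 and 1.34, and Lrrc15 fell by 1.11. Pdk1, encoding a kinase that restrains pyruvate dehydrogenase, fell by 0.69 and 0.61. Lists without a camera call in either treatment included 2-oxoglutarate-dependent dioxygenases (3 of 35 risen in each) and nuclear-encoded respiratory chain genes (4 and 6 of 76 risen, 2 and 3 fallen). The median and mean differed in sign for p53 targets (-0.06 and 0.02) in untreated cells and for TCA cycle and 2-hydroxyglutarate enzymes (-0.03 and 0.07) under myxothiazol, neither of which passed. L2hgdh itself, with a log2 fold change of 2.87 under myxothiazol, is a member of the latter list, in mESCs as in kidney and liver. Genes called in both treatments in the same direction numbered 421 risen and 351 fallen of 13647, against 40 and 32 for independent lists (r = 0.57, rho = 0.53 across genes). Both comparisons set L2HGDH cells against EV cells, so other differences between these populations would be shared as well. For the calls as a whole they cannot be told apart from an effect of the cDNA. Fallen genes were unevenly placed: chromosomes 3 and 6 held 9.48% of tested genes and 39.3% of fallen genes in untreated cells, and 9.45% and 37.9% under myxothiazol. Without chromosomes 3, 6, 8 and Y, 838 and 849 genes were called. Leaving out a single library lowered the untreated count to 934 (EV 1), 927 (EV 3), 965, 936 and 941 (L2HGDH 1, 2 and 4), and the myxothiazol count to 867 (EV 1), 903 and 847 (L2HGDH 1 and 4). Of 8 measured genes of the Y chromosome 7 rose in each treatment, among them Kdm5d (1.91 ± 0.19 under myxothiazol).

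**Figure D3:**
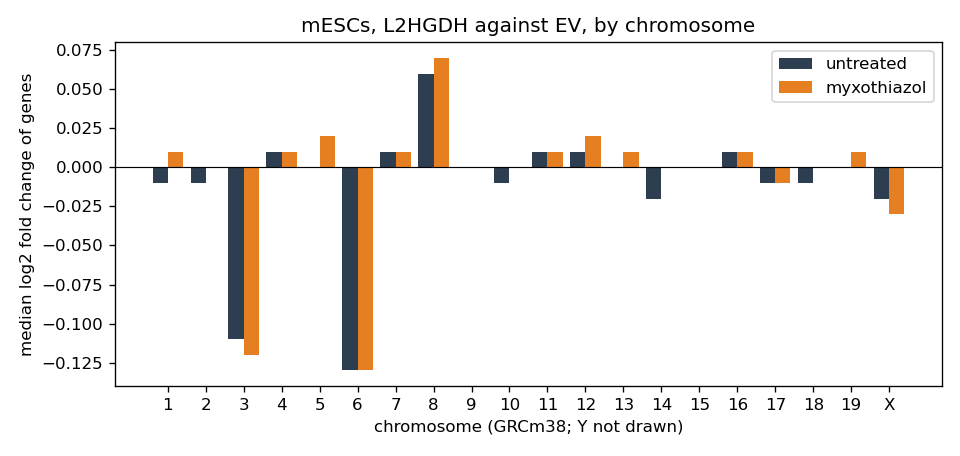
Median log2 fold change of tested genes, L2HGDH against EV, by chromosome (GRCm38, Y not drawn), in untreated and myxothiazol mESCs (bars). Chromosome 6 had a median of -0.13 in both treatments and chromosome 8 medians of 0.06 and 0.07.

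The interaction of cDNA and myxothiazol called 0 of 14793 genes with edgeR; 914 had an unadjusted p under 0.05, against 740 by chance, and DESeq2 called 11, 3 higher and 8 lower. The smallest p-values belonged to Rapgef1 (log2 difference -0.30 ± 0.05 SE, adjusted p = 0.575), Ahcyl2 (-0.60 ± 0.12) and Grb10 (-0.30 ± 0.06). Germline genes (median 0.09, 17 of 21 positive) and p53 targets (median 0.07, 15 of 21 positive) passed camera (adjusted p = 0.00488 and 0.0157, and adjusted p = 0.15 and 0.17 with an estimated correlation).

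In kidney 8 genes rose and 0 fell of 16306 with edgeR; 1347 had an unadjusted p under 0.05, against 815 by chance, and DESeq2 called 44 risen and 21 fallen. Besides L2hgdh the risen genes were Trib3, Chac1, Atf5, Nupr1, Slc1a4, Gt(ROSA)26Sor and Trim66, the last named after its value was seen. Trim66 was 2.52 ± 0.846 against 0.104 ± 0.0741 CPM (SD, n = 5 each; log2 fold change 4.50 ± 0.43 SE). Trib3, a pseudokinase gene induced by stress, was 16.7 ± 12.2 against 1.19 ± 0.445 CPM (SD, n = 5 each; log2 fold change 3.77 ± 0.53 SE, adjusted p = 0.0381), and Chac1, which encodes a glutathione-degrading enzyme, 4.13 ± 1.98 against 0.323 ± 0.163 CPM (3.60 ± 0.45, adjusted p = 0.0282). Atf5, an ATF family transcription factor gene, rose by 1.78 ± 0.21 (adjusted p = 0.0248). The amino acid transporter gene Slc1a4 was 20.6 ± 3.92 against 8.65 ± 2.28 CPM, and the stress gene Nupr1 17.2 ± 1.86 against 9.84 ± 1.48 CPM (SD, n = 5 each). Gt(ROSA)26Sor, a noncoding transcript of the Rosa26 locus, was 19.2 ± 3.28 against 4.93 ± 2.36 CPM. Asns, encoding asparagine synthetase, and Slc7a5 had log2 fold changes of 2.34 ± 0.39 and 1.60 ± 0.28 without passing (adjusted p = 0.133 and 0.166).

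Of 33 ATF4 targets in kidney 4 rose over all genes and 15 adjusted over the list alone (median 0.38; adjusted p = 7.43e-13, and adjusted p = 0.19 with an estimated correlation). Interferon-stimulated genes (0 of 31 called by edgeR, 12 higher adjusted over the list alone; median 0.49), tubular injury genes (6 of 17 higher and 1 lower adjusted over the list alone; median 0.90) and leukocyte markers (median 0.32) had adjusted p = 3.97e-14, 2.38e-05 and 0.000264 upward, and adjusted p = 0.29, 0.25 and 0.65 with an estimated correlation. Red blood cell markers (5 of 8 lower adjusted over the list alone; median -0.86) had adjusted p = 9.08e-11 downward, and adjusted p = 0.13 with an estimated correlation. Without wild-type kidneys 2 and 3 these 5 lists kept their direction, with adjusted p of 6.88e-06 or lower, and adjusted p = 0.31 to 0.44 with an estimated correlation. The tubular injury median was then 0.47, with 3 of 17 higher adjusted over the list alone, and the leukocyte median 0.53, with 9 of 25 higher adjusted over the list alone.

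Nuclear-encoded respiratory chain genes were negative for 76 of 76 members in kidney (median -0.36, adjusted p = 1.59e-20). TCA cycle and 2-hydroxyglutarate enzymes (median -0.34), proximal tubule markers (median -0.53), podocyte markers (median -0.33) and sterol synthesis genes (median -0.13) had adjusted p = 4.22e-08, 0.000184, 0.00768 and 0.00231 downward. With an estimated correlation the first 4 of these lists had adjusted p = 0.65 and the sterol list adjusted p = 0.74. Beside these lists, wild-type kidneys 2 and 3 stood apart, with mean proximal tubule marker levels of 8.85 and 9.06 on the log2 scale against 7.80 to 8.37 in the other 8. Without them the respiratory chain median was -0.06 (adjusted p = 0.00125, and adjusted p = 0.73 with an estimated correlation) and the proximal tubule median 0.02 with a downward test (adjusted p = 0.518), and the TCA, podocyte and sterol lists had adjusted p = 0.223, 0.0961 and 0.075. With sex as a covariate the respiratory chain median was -0.27. Collecting duct markers (median -0.09, mean 0.01) and circadian clock genes (0.01 and -0.05) did not pass. Without wild-type kidneys 2 and 3 both passed upward (medians 0.16 and 0.12, adjusted p = 0.008 and 0.0182), and each had adjusted p = 0.44 with an estimated correlation. Mitochondrially encoded mRNAs, positive for 0 of 13 members with all kidneys (adjusted p = 0.183), were then positive for 13 of 13 (median 0.24, adjusted p = 0.000343), and extracellular matrix genes, positive for 18 of 24 (median 0.09, adjusted p = 0.199), were negative for 19 of 24 (median -0.17, adjusted p = 6e-04). Cell cycle genes were negative for 20 of 20 (median -0.42, adjusted p = 7.91e-08). These 3 lists had adjusted p = 0.55, 0.55 and 0.44 with an estimated correlation. The other lists that passed in that fit but not with all kidneys were thick ascending limb and distal convoluted tubule markers, NRF2 targets, genes of fatty acid oxidation and immediate early genes upward (adjusted p = 0.000351, 0.000366, 0.018 and 0.0182) and endothelial markers downward (adjusted p = 0.0215), with adjusted p = 0.44 to 0.72 with an estimated correlation.

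The kidney count of called genes was 3 with sex as a covariate, 4 without wild-type kidneys 2 and 3, and 1 without wild-type kidneys 1 and 5, where brown fat genes were high. It was 2 without overexpressing kidney 5 or wild-type kidney 1, 2 or 4, 3 without overexpressing kidney 1 or wild-type kidney 3 or 5, and 4 without overexpressing kidney 3. The calls of Trib3 and Atf5 were lost without overexpressing kidney 1 or 5 or any wild-type kidney, and that of Chac1 also without overexpressing kidney 3. The Slc1a4 call was lost without any kidney but overexpressing kidney 2, the Nupr1 call without any kidney, and the Gt(ROSA)26Sor call without any kidney but wild-type kidneys 3 and 5. Asns passed without overexpressing kidney 2. L2hgdh was called in each of these fits. Trim66 was not followed through them.

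**Figure D4:**
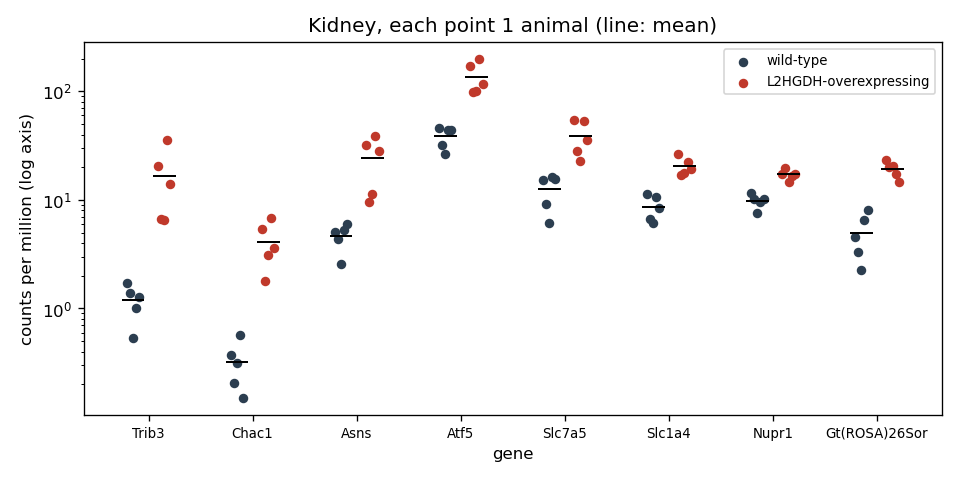
Levels in CPM (log axis) of 8 genes in kidney of wild-type and L2HGDH-overexpressing mice; points are animals (n = 5 per group) and lines are means. Trib3 had means of 16.7 CPM in overexpressing and 1.19 CPM in wild-type mice; Asns and Slc7a5 did not pass.

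In liver L2hgdh was the only call of 12996 genes with edgeR; 1386 had an unadjusted p under 0.05, against 650 by chance, and DESeq2 called 58 risen and 35 fallen. The next smallest p-values belonged to Cd163, a macrophage scavenger receptor gene (log2 fold change -1.35 ± 0.22 SE), Fst (1.72 ± 0.28), Ramp1 (1.34 ± 0.23) and the chemokine gene Cxcl10 (1.66 ± 0.29), each with adjusted p = 0.205. DESeq2 and edgeR shared 1 call, and 2 genes were called by edgeR without overexpressing liver 5.

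Sterol synthesis genes in liver were negative for 24 of 24 members (median -0.76; 0 called by edgeR, 11 lower adjusted over the list alone), with adjusted p = 2.43e-12 and adjusted p = 0.39 with an estimated correlation. Without overexpressing liver 4, or without wild-type livers 2 and 3, 24 of 24 were still negative (medians -0.62 and -0.70). In both fits, with fewer samples, 0 were lower adjusted over the list alone. Without wild-type liver 3 alone, also with fewer samples, 11 of 24 were lower adjusted over the list alone (median -0.8). Interferon-stimulated genes (median 0.40, 12 of 31 higher adjusted over the list alone), ATF4 targets (median 0.34) and leukocyte markers (median 0.32) had adjusted p = 9e-09, 0.000203 and 1.48e-05 upward, and adjusted p = 0.39, 0.53 and 0.39 with an estimated correlation. Overexpressing liver 4 stood apart beside the ATF4 list, with Trib3 at 63.1 CPM and Asns at 107 CPM against at most 10.6 and 48.5 CPM in the other 9 livers. Without it the ATF4 median was 0.10, with 21 of 32 members positive (adjusted p = 0.0218, and adjusted p = 0.49 with an estimated correlation). Red blood cell markers (median -0.86), pericentral hepatocyte genes (median -0.49, 3 of 17 lower adjusted over the list alone), endothelial markers (median -0.31) and stellate cell markers (median -0.21) had adjusted p = 0.000123, 0.000172, 0.00049 and 0.0199 downward, and adjusted p = 0.39 for each with an estimated correlation. Extracellular matrix genes (median -0.23) and genes of fatty acid oxidation (median -0.12) had adjusted p = 0.00539 and 0.0183 downward, and adjusted p = 0.62 and 0.81 with an estimated correlation. Without overexpressing liver 4 their medians were -0.15 and -0.21, and the matrix list did not pass (adjusted p = 0.129). Acute phase genes had a median of 0.20 and a mean of -0.65, with adjusted p = 0.00049 upward and adjusted p = 0.58 with an estimated correlation; Saa1 was 3330 CPM in wild-type liver 3 and 2.86 to 7.3 CPM in the other wild-type livers. Genes of gluconeogenesis and amino acid catabolism had a median of -0.19 and an upward test that did not pass (adjusted p = 0.824). Without wild-type livers 2 and 3 both lists passed upward: acute phase genes had a median of 0.54 and a mean of 1.36, with 18 of 19 positive (adjusted p = 1.96e-08), and gluconeogenesis genes a median of 0.46, with 20 of 22 positive (adjusted p = 0.000435). Each had adjusted p = 0.58 with an estimated correlation in that fit, where the pericentral median was -0.29. Periportal hepatocyte genes (median 0.53) and respiratory chain genes (0.12) upward and cell cycle genes (-0.32) downward, which did not pass with all livers, passed there too (adjusted p = 0.000608, 0.000346 and 0.00449, and adjusted p = 0.58, 0.65 and 0.65 with an estimated correlation).

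Female-biased liver genes (median -0.69, 2 of 20 lower adjusted over the list alone), lipogenesis genes (median -0.30) and TCA cycle and 2-hydroxyglutarate enzymes (median -0.15) also had adjusted p = 0.000383, 0.00609 and 0.00415 downward, and adjusted p = 0.39, 0.39 and 0.62 with an estimated correlation. Of the wild-type mice 3 were female, against 2 of the overexpressing mice, and with sex as a covariate the female-biased list had adjusted p = 0.000518. Without wild-type livers 2 and 3 these lists had adjusted p = 0.0669, 0.192 and 0.477.

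The genotype effect differed between kidney and liver for 0 of 16483 genes with edgeR, and for 0 with the animal as a block; 1319 had an unadjusted p under 0.05, against 824 by chance, and DESeq2 called 32, 18 higher and 14 lower. With sex as a covariate 2 genes were called, and 1, 2, 1 and 1 without kidney OE 4, kidney WT 1, liver OE 4 and liver WT 5 (OE, overexpressing; WT, wild-type). L2hgdh differed by 0.29 ± 0.34 on the log2 scale (adjusted p = 0.851). Respiratory chain genes (median -0.35), sterol synthesis genes (0.68) and extracellular matrix genes (0.30) passed camera (adjusted p = 1.45e-13, 1.24e-07 and 0.00299), and each had adjusted p = 0.87 with an estimated correlation. The list tests between tissues did not take the pairing of kidney and liver by animal into account. Beside the respiratory chain and matrix lists, wild-type kidneys 2 and 3 stood apart from the other kidneys. Without these 2 animals in both tissues the respiratory chain median was -0.17 and the sterol median 0.65 (adjusted p = 4.19e-07 and 5.66e-07, and adjusted p = 0.98 for each with an estimated correlation), and the matrix list did not pass (median 0.14, adjusted p = 0.602). Genes of fatty acid oxidation (median 0.41), endothelial markers (0.28) and exocrine pancreas markers (-1.07) then passed (adjusted p = 0.000316, 0.00319 and 0.0496, and adjusted p = 0.98, 0.98 and 0.50 with an estimated correlation). Cell cycle genes had a median of -0.10 and an upward test that did not pass (adjusted p = 0.963). Kidney and liver fold changes, from the same animals, correlated with r = 0.20 and rho = 0.16 across genes, and L2hgdh was the only gene edgeR called in both; genes are not independent replicates.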

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

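Tests chosen after the result was seen were those of Y chromosome loss, of regulation of single genes, of all 4 explanations for wild-type kidneys 2 and 3, and the splits counted without L2hgdh. The list tests without these animals or with sex as a covariate were added after seeing the data. Of 450 gene and group pairs tested for a library far from the others, 25 held one, and chance gives about 1 in 20 groups, or 22.

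In mESCs with L2HGDH, genes of chromosomes 3 and 6 were lower and those of 8 and Y higher than with EV, in both treatments. Regulation of single genes without regard to chromosome is argued against by the share of fallen calls on chromosomes 3 and 6, which was at least 4.01 times their share of tested genes, while the highest such ratio of any 2 chromosomes was 1.66 and 1.68 in 1000 random placements of the calls of each treatment. A difference in copy number may account for the autosomes: with each chromosome in 3 parts, the highest median log2 fold change of the parts of chromosomes 3 and 6 was -0.056 and the lowest of chromosome 8 was 0.034, so the shift ran along each chromosome, but DNA was not measured. Loss of the Y chromosome in part of the EV cells cannot be told apart from regulation of its genes, since 14 of 16 values were positive and 1 of 8 genes in each treatment was not. Whether the cDNA itself brought about the chromosome shifts was not tested.

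Wild-type kidneys 2 and 3 stood apart, with Wnt gene means of 1.63 and 1.27 on the log2 scale against 4.11 or more in the other 8 kidneys. Genotype alone as the cause is argued against, since 2 of the 5 wild-type kidneys lay above the highest overexpressing kidney in proximal tubule minus collecting duct markers and the other 3 (2.05 to 2.34) lay within the overexpressing range (1.52 to 2.41). A state of the whole animal such as maturity may apply to the animal of kidney 3, whose fetal liver genes lay at -3.1 relative to the lowest other liver. In the animal of kidney 2 the value was 0.13 relative to the lowest of the other 8 livers. Its single fetal liver genes were mixed: Gpc3 and Igdcc4 (157 and 3.29 CPM) were lower than in those 8 livers, and Afp, H19, Igf2 and Dlk1 were not. The value is from a single liver close to the lowest, so it cannot decide the question for that animal. Age is not in the labels, so a difference in age between the animals could not be checked. Another share of cortex and medulla cannot be told apart from other causes: the marker difference exceeded that of the other kidneys by 0.46 or more, but collecting duct markers were not lower (5.98 and 6.13 against 5.79 to 6.28).

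ATF4 targets were higher in L2HGDH-overexpressing kidneys. Wild-type kidneys 2 and 3 as the whole cause are argued against, since without them 32 of 34 targets were still positive (median 0.35). Camera with the preset correlation then gave adjusted p = 8.16e-16. Sex as the whole cause is argued against too: with it as a covariate 28 of 33 were positive (median 0.33, camera adjusted p = 2.78e-13). Overexpressing kidney 4, of the same animal as overexpressing liver 4, had the highest Trib3 and Asns levels (36 and 39 CPM). The list was not tested without that kidney. In the other overexpressing kidneys Trib3 was 6.47 to 20.6 CPM and Asns 9.57 to 32.4 CPM. Wild-type kidneys had at most 1.72 and 5.96 CPM. An effect of genotype stays open as a hypothesis. With an estimated correlation the list did not pass with all kidneys (adjusted p = 0.19), without wild-type kidneys 2 and 3 (adjusted p = 0.31) or with sex as a covariate (adjusted p = 0.23). The fry test, which does not compare a list with other genes, gave adjusted p = 0.017, 0.13 and 0.04 in the same order.

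Other splits of the same libraries were refitted for each count. For the cDNA in untreated mESCs 1 of 35 splits, the real one, called as many genes (1448, highest other 1), and under myxothiazol 1 of 35 (1392, highest other 2). For myxothiazol it was 1 of 35 in EV cells (5605, highest other 2) and 1 of 35 in L2HGDH cells (5566, highest other 2). Chance labelling of these libraries can thus be excluded for these counts. The libraries of a group may not be separate cultures, so the splits cannot exclude chance differences between cultures or cell populations. For the kidney count, chance labelling without regard to sex can also be excluded (8 genes, 1 of 100 drawn splits, highest other 2). The same holds for it without L2hgdh (7 genes, 1 of 100, highest other 2). With splits within sex the count was 3 (1 of 100; highest other 2), of which L2hgdh is 1; without it the count was 2, which another split also reached (2 of 100; highest other 2). A count that another split reached is weak evidence against chance for the calls besides L2hgdh. The kidney count, L2hgdh included, fell to 2 on leaving out single kidneys. The liver count alone does not exclude chance (11 of 100; 1, highest other 12), but splits that call any gene do not test the call itself, L2hgdh, which was higher in 5 of 5 overexpressing livers than in every wild-type liver and was called with each library left out (log2 fold change 3.73 to 4). The interactions called 0 genes, so all 100 of 100 splits called as many by construction, in mESCs (highest other 1062) and in tissues (highest other 2), which says nothing about chance. The split with 1062 calls kept the L2HGDH label on 4 of 4 myxothiazol and 1 of 4 untreated L2HGDH libraries, so the difference between the cell populations entered it.

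In untreated EV cells BB287469 was 0.559 CPM in library 2 and 2.56 to 2.91 in the others. Zscan4d was 2.5 CPM in library 1 and 1.08 to 1.31 in the others. Lss was 177 CPM in library 1 and as low as 115 in the others. Trim66 was 0.66 CPM in library 4 and 0.808 to 0.834 in the others. In untreated L2HGDH cells Dnmt3a was 160 CPM in library 4 and 167 in the others. Hoxd8 was 0.856 CPM in library 4 and 0.433 to 0.449 in the others. Aurkc was 10.1 CPM in library 2 and 8.25 to 8.43 in the others. In myxothiazol EV cells Usp17ld was 0.221 CPM in library 4 and 0.0558 to 0.0622 in the others. Sox2 was 364 CPM in library 3 and 378 to 380 in the others. Uqcrh was 58 CPM in library 1 and 50.2 to 51 in the others. Eln was 4.29 CPM in library 2 and 5.19 to 5.35 in the others. Pdgfrb was 6.55 CPM in library 3 and 4.86 to 5.1 in the others. mt-Co2 was 3580 CPM in library 4 and 3210 to 3230 in the others. In myxothiazol L2HGDH cells D2hgdh was 15.5 CPM in library 4 and 13.9 to 14.2 in the others. Zscan4c, Aurkc, Pdgfrb and Adhfe1 were 12, 3.02, 9.81 and 4.26 CPM in library 3 and 7.09 to 7.83, 1.84 to 1.99, 8.91 to 9 and 1.9 to 2.17 in the others. Ahcyl2 was 62.4 CPM in library 1 and 52.1 to 53.4 in the others.

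In overexpressing kidneys D2hgdh was 54.8 CPM in library 4 and 18.5 to 26.6 in the others, and C8a was 1.55 CPM in library 2 and 0.456 to 0.76 in the others. In wild-type kidneys Apoh was 0 CPM in library 2 and 0.0299 to 0.0314 in the others, and Itgav was 308 CPM in library 3 and 201 to 216 in the others. Rarres1 was 23.4 CPM in wild-type liver 1 and 19.2 to 20.2 in the others. Siglec1 was 16.3 CPM in overexpressing liver 3 and 9.49 to 11.1 in the others. Lists whose effect differed between treatments were germline genes (adjusted p = 0.00488) and p53 targets (adjusted p = 0.0157). Between kidney and liver, respiratory chain genes (adjusted p = 1.45e-13), sterol synthesis genes (adjusted p = 1.24e-07) and extracellular matrix genes (adjusted p = 0.00299) differed, and none of these 5 passed with an estimated correlation. Without wild-type animals 2 and 3 the matrix list did not pass between tissues (adjusted p = 0.602).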

How the results depend on the processing

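Alternatives without chromosomes 3, 6, 8 and Y or without chosen animals were chosen after seeing the data, as were list tests with sex as a covariate. L2hgdh kept its direction in every alternative; in EV cells its change with myxothiazol lost its call with no filter (-0.18) and on leaving out libraries (-0.22 to -0.13), and the cause was not tested. Without those chromosomes, where fewer genes are tested, the cDNA called 838 genes in untreated and 849 in myxothiazol cells; single libraries left out gave 927 to 1096 and 847 to 1221, with fewer samples. DESeq2 called 11 genes for the mESC interaction, 65 in kidney, 93 in liver, 32 for the tissue interaction and 3 in both tissues; the cause was not tested. The kidney count was 3 with sex as a covariate, 4 without wild-type animals 2 and 3, 1 without wild-type animals 1 and 5 and 2 to 8 on leaving out a library; the liver count was 1 to 2, and the tissue interaction 2 with sex, 1 without wild-type animal 3 and 0 to 2 without single libraries. With an estimated correlation the number of passing lists went from 5 to 0 (cDNA, untreated; 2-cell-like and Hox genes passed without those chromosomes), 7 to 2 (cDNA, myxothiazol), 4 to 0 (myxothiazol, EV), 5 to 0 (myxothiazol, L2HGDH), 2 to 0 (mESC interaction), 10 to 0 (kidney), 14 to 0 (liver) and 3 to 0 (tissue interaction). The fry test, which does not compare a list with other genes, passed 8, 14, 12, 0, 2, 0 and 1 lists in the same order without the second. Without wild-type animals 2 and 3 camera with the preset correlation passed 16 kidney lists (10 gained, 4 lost), 15 liver lists (4 gained, 3 lost) and 5 lists of the tissue interaction (3 gained, 1 lost), and without overexpressing animal 4 it passed 13 liver lists (1 lost); in these fits no list passed with an estimated correlation (lowest adjusted p 0.31, 0.58, 0.5 and 0.49) or with fry (0.11, 0.17, 0.062 and 0.41). D2hgdh, not called in any comparison, changed sign: on leaving out libraries -0.24 to 0.07 (myxothiazol, L2HGDH cells), -0.45 to 0.07 (kidney), -0.15 to 0.38 (liver) and -0.63 to 0.07 (tissue interaction), and 0.18 in kidney without wild-type animals 2 and 3, -0.04 in liver with sex and -0.08 in liver without wild-type animal 3 and overexpressing animal 4. Of the values of other named genes under an alternative 2827 kept their direction and side of the threshold, 263 lost and 35 gained a call, and 0 reversed. Replicate numbers did not pair mESC libraries (same-number correlations -0.12 to 0.06; 0 or 1 of 4 correlated best with their own number), kidneys (-0.24 to 0.30) or livers (-0.13 to 0.04); as a block they gave 499 calls for the cDNA under myxothiazol and an L2hgdh change of -0.18 in EV cells that was not called, and with the animal as a block the tissue interaction had 0 calls. Livers had the lowest totals, from 12513238 counts, and whether depth limited the calls there was not tested on the data. On simulated counts 74% of 2-fold changes were recovered in liver and in kidney alike. Only genes with a mean above 5 CPM were changed there, so a limit on genes with lower levels could not show. That share holds for the number of genes changed in the simulation. In the real data Asns in kidney and Fst in liver, with log2 fold changes of 2.34 and 1.72, were not called.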

Other observations

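The kidney test of the hypothesis on genes raised by myxothiazol was chosen after the result was seen. Brown fat genes were high in a pair of wild-type kidneys. Ucp1, the uncoupling protein of brown fat, was 55.4 CPM in wild-type kidney 5 and 10.3 CPM in wild-type kidney 1, and at most 1 CPM in the other 8 kidneys. Cidea was 24.5 and 4.32 CPM there, and the fat cell genes Adipoq and Plin1 were 9.8 and 11.1 CPM in kidney 5 and 3.01 and 2.29 CPM in kidney 1. Gt(ROSA)26Sor was 4.4 to 6.38 CPM in overexpressing livers and 1.11 to 4.79 CPM in wild-type livers.

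Wild-type liver 3 had low levels of genes that are high in the fetal liver: Afp was 5.11 CPM, H19 1160 CPM and Igf2 98.6 CPM, against at least 206, 7080 and 1540 CPM in the other 9 livers. The clock genes Dbp and Arntl were 89.7 and 2.97 CPM there, against 11 to 74.4 and 4.06 to 15 CPM in the other 9 livers, where overexpressing liver 1 came closest. They were 79 and 3.92 CPM in the kidney of the same animal, against 18.4 to 38 and 11 to 17.1 CPM in the other 9 kidneys. In wild-type kidneys 2 and 3 Wnt4 was 1.39 and 1 CPM, Wnt7b 3.61 and 2.48 CPM and Wnt11 0.562 and 0.345 CPM, against at least 11.2, 30.4 and 12.7 CPM in the other 8 kidneys.

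Genes raised by myxothiazol in mESCs may also be higher in L2HGDH-overexpressing tissue, which was examined with 4 tests of this set of 299 genes by camera (limma) with an estimated correlation. In kidney 153 of 258 measured genes were positive (median log2 fold change 0.07), with p = 0.034 before and adjusted p = 0.14 after adjustment over the 4 tests with an estimated correlation, so the set did not pass. Without ATF4 targets 140 of 243 genes were positive in kidney (median 0.06; p = 0.1, adjusted p = 0.19 with an estimated correlation). In liver 89 of 197 genes were positive, with the test pointing down (median -0.06; p = 0.35, adjusted p = 0.35 with an estimated correlation), and without ATF4 targets 78 of 185 (median -0.08; adjusted p = 0.19). None of the 4 tests passed after adjustment.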
